A study of Arabidopsis thaliana with 6 samples.

How the data were processed

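RNA from 6 Arabidopsis thaliana cultures (ecotype Ler) was hybridised to 1-colour ATH1 arrays, with 1 array for each of 6 conditions. Per the labels' protocols, leaves of 14 to 17 day old seedlings were kept on callus induction medium (2.0% glucose, 0.5 mg/l 2,4-D, 0.05 mg/l kinetin) in darkness at 22 °C for 2 weeks, which gave the day 0 sample. Callus was then moved to liquid medium on a shaker at 105 rpm. The medium that the labels call high differentiating held 0.2% sucrose, 4% mannitol, 0.2 mg/l auxins and 1 mg/l of the cytokinin benzyladenine (BA). The low differentiating medium held the same sucrose and mannitol with 0.5 mg/l 2,4-D and 1.5 µg/l kinetin. The labels leave open whether 0.2 mg/l is the amount of each auxin or their sum, how the liquid cultures were lit, and which cell type was formed. Their growth field gives the auxins and BA of the high medium for all 6 samples, and their extraction text speaks of seedlings, so the medium of each sample was taken from its name and its treatment text.

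The deposited values are intensities on a linear scale, with 1 value for each of 22810 probe sets. The software that summarised and scaled them is not given in the sources used here. The deposited intensities had been scaled to a common level, since the mean after trimming 2% at each end, over the 22746 probe sets that are not controls, ran from 99.2 to 99.4. That agreement lay within the 5% limit set beforehand, so the scaling was kept. A common floor was placed at an intensity of 24.7, the median over arrays of the 40th percentile, and log2 was taken. A ratio with 1 array at the floor is a lower bound, written as at least, and no ratio is given for a gene where both lay at the floor. Between 59.3% and 61.1% of probe sets lay above the floor on each array. The number of arrays, not a read depth, limits the precision.

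The platform annotation used here gives 1 gene for 13513 of these probe sets and several genes for 503. The other 8730 (38.4%) are unnamed here. Of the single-gene probe sets, 13436 were matched by gene identifier to the RefSeq table of assembly TAIR10.1, which was used for names only. After the probe set with the highest mean signal was kept for each gene, 13355 genes remained. Probe sets with several genes were counted but not named.

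A probe set was called different when 2 arrays differed at least 2-fold. With 1 array per condition this is a rule of size, with no replicate check and no p-value. The planned test of medium used limma (version 3.58.1, R 4.3.3) on the 4 arrays of days 5 and 9, with day as a covariate, a variance trend and Benjamini-Hochberg adjustment at 0.05. Its 1 residual degree of freedom is the change of the medium difference between the days, so it holds no replicate error. In simulated data with 200 probe sets changed between media on both days, run on 22746 probe sets, the planned fit recovered 0% of changes of 2-fold, 4-fold or 8-fold. It therefore could not detect changes of these sizes. A fit without probe sets at the floor on all 4 arrays recovered 0% of 2-fold, 95.5% of 4-fold and 98.5% of 8-fold changes, with 0 false calls. This second fit was not planned. It was run first by mistake, so its result was known before that of the planned fit, which remains the main one. The 2-fold rule applied to both days recovered 26.5% of simulated 2-fold and 98.5% of 4-fold changes, with 0 false calls. In all these simulations the changed probe sets were drawn from those more than 2-fold above the floor on all 4 arrays. Recovery of dimmer probe sets was not tested. Each simulated change was the same on both days, and noise was drawn from probe sets of like brightness. A spread particular to a probe set was therefore not modelled, and recovery in the real arrays may be lower.

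Gene lists were described by their median log2 ratio and its percentile among 10000 random lists of the same size, matched on mean log2 signal in 20 bins. In these medians a member at the floor on both arrays counts as 0, so a list with many such members is held at or near 0.00 and cannot be read as unchanged. A list outside the central 95% is said to stand apart. Among 150 random lists of 20 bright genes, drawn from the same arrays, 5.24% of medians fell outside. This checks the procedure only, since random lists were ranked among random lists. It does not cover lists whose members vary together. Shorter lists and lists with dim members were not checked in this way. Before the data were examined, 20 lists of 330 genes were fixed, but only 47 of these genes are paired with a probe set in the annotation used here, and 8 lists kept 3 or more. A further 24 lists were added after the annotation was seen. Of these, 22 were written before their values were computed, although an early view of single rows had shown 1 mitochondria-encoded gene. The other 2, heat-shock and chaperone genes and endoplasmic reticulum stress genes, were written after heat-shock genes were seen to lead the named genes in comparisons with day 0. The lists with 3 or more members gave 224 medians over 7 comparisons. Of these, 53 stood apart, among them all 7 of the heat-shock and chaperone list. In 13 added lists members at the floor held the median at 0.00 in every comparison.

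Named genes followed a rule fixed beforehand. It took the 12 highest and 12 lowest genes between media by the smaller of the ratios at the 2 days, and the 5 highest and 5 lowest in each comparison with day 0. It also took up to 3 genes in each order that were 2-fold different in opposite directions at days 5 and 9, up to 4 members of each list per comparison, and the reference genes. MYB46, VND6, VND7, CESA4, CESA7, CESA8, XCP1 and XCP2 belonged to the rule but are not reported here, since the annotation used pairs none of them with a probe set. Alternatives were quantile scaling, equal array medians, floors at the 20th and 60th percentiles, and no floor with 16 added before log2. For limma they were also no day term, no variance trend and a filter on dim probe sets. For lists they were also the mean over a gene's probe sets and members above the floor only. Overlaps between comparisons with day 0, which share 1 array, were set beside 100 simulations of unchanged arrays with the noise of the medium-by-day contrast. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 were used.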

Results

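The series followed cultured Arabidopsis cells after callus was moved into liquid medium, under a title that speaks of trans-differentiation. Arrays were read for callus at day 0, for high differentiating medium at days 2, 5 and 9, and for low differentiating medium at days 5 and 9, with 1 array each. No difference below therefore has a replicate check. Across probe sets, which are not independent replicates, the day 0 array had Pearson correlations of 0.951 to 0.967 with the liquid cultures, and the media correlated at 0.984 on day 5 and 0.990 on day 9. The reference genes TIP41L and SAND stayed between 191 and 214 and between 113 and 137 in intensity.

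The first comparison asked how the media differed at matched times. Of the probe sets called, 58.0% at day 5 and 60.6% at day 9 are unnamed here, so only named genes could be ranked. AT3G27200, a plastocyanin-like gene, read 371 in high and 84.5 in low medium at day 5, and 201 against 67.5 at day 9, log2 ratios of 2.14 and 1.58. The peroxidase gene AT5G51890 was higher in high medium by 1.86 and 1.43 on the log2 scale, and AT3G10080, a germin-like gene, by 2.76 and 1.31. AT4G27435 had log2 ratios of 1.36 and 1.30, and AT3G54040 of 1.64 and 1.11. The dehydrin gene COR47 was the leading named gene in the other direction. It read 71.6 in high against 227 in low medium on day 5 and 66.9 against 228 on day 9. AT5G47600 lay at the floor in high medium on both days and read 68.0 and 67.1 in low medium, so it was lower by a log2 ratio of at least 1.46 and 1.44 in size.

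Other genes higher in high medium at both days were AT2G04850, with log2 ratios of 1.31 and at least 1.49, AT5G59845 with 1.37 and 1.35, and AT3G19370 with 1.10 and 1.14. AT1G75280 had 1.10 and 1.39, AT2G40530 had 1.36 and 0.99, AT1G43910 had 1.13 and 0.97, and the peroxidase gene AT2G34060 had 1.41 and 0.93. Among genes lower in high medium, AT1G56680, of a chitinase family, had log2 ratios of -1.76 and -1.14, AT2G34080, a cysteine protease gene, -1.03 and -1.68, and AT4G00750 -1.27 and -1.05. The glycosyl hydrolase gene GH9B13 had -2.05 and -0.87, and the auxin response repressor gene IAA20 had -0.88 and -1.40. AT1G54020, AT1G12600, TRM24, JRG21 and AT1G63950 completed the lower 12, with day 9 log2 ratios of -1.35, -1.08, -1.03, -0.87 and -0.90.

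**Figure D1:**
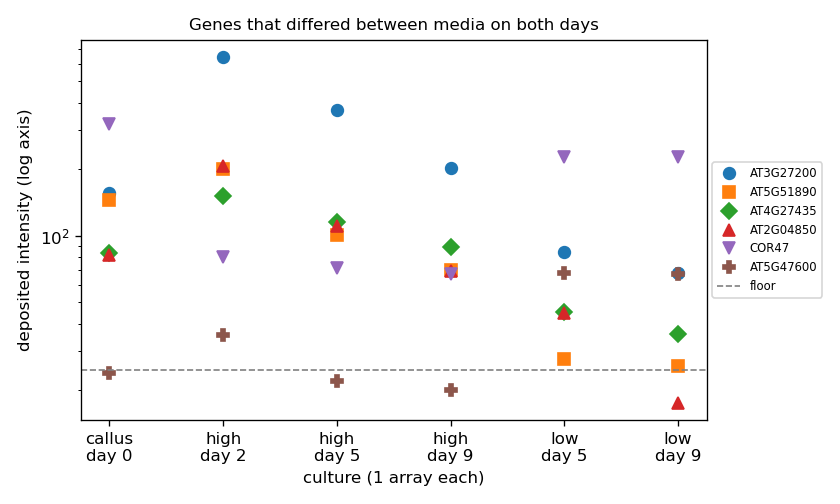
Deposited intensity on a log axis for 6 genes in the 6 cultures, with 1 point per array and the floor of 24.7 as a dashed line. AT3G27200 read 371 in high and 84.5 in low medium at day 5, and COR47 read 71.6 and 227.

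A set of genes known for co-expression with secondary wall formation, listed by locus, stood apart in this comparison, while the secondary wall list fixed beforehand, with 3 measured genes, did not (medians of 0.22, percentile 90.5, at day 5 and 0.07, percentile 70.8, at day 9). Of the 21 measured members by locus, 5 were at least 2-fold higher in high medium at day 5 and 3 at day 9, and 0 were 2-fold lower on either day. The median log2 ratio was 0.22 at day 5 and 0.21 at day 9 (percentile 100 among matched random lists on both days). AT3G27200 and AT4G27435 belong to this set, as do AT1G79620, at 59.1 against 19.9 at day 5, and AT5G26330, at 60.2 against 15.8. Both of these low medium values lay below the floor, so the ratios of AT1G79620 and AT5G26330 are lower bounds. With a floor at the 60th percentile both medians were 0.00 and the set no longer stood apart. The zinc finger gene C3H14, from the list of xylem transcription factors, had log2 ratios of 0.77 and 0.45. In the list of xylem cell death, with 4 measured genes, SCPL48 had -0.66 and -0.41, and the list did not stand apart between media. Against callus it stood apart at day 5 in both media, with medians of 0.45 in high and 0.53 in low medium.

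Of the 8 measured genes of the auxin response list, 5 read lower in high medium at day 5, and the list median was -0.73 (percentile 0.00). At day 9 the median was -0.07, within the central 95% of random lists, although 6 genes still read lower in high medium and 1 higher. GH3.5, which encodes an auxin-conjugating enzyme, read 969 in high and 2025 in low medium at day 5, and 1956 and 2027 at day 9. LBD16 read 95.3 and 170 at day 5. All 4 measured genes of the photosynthesis list read higher in high medium at day 9, with a median of 0.74 (percentile 100), and LHCB4.1, a light-harvesting protein gene, read 65.2 against 30.9. With a floor at the 60th percentile this list no longer stood apart, and at day 5 it did not either. In a wider list of 24 nuclear photosynthesis genes at day 9, 10 were higher, 3 lower and 11 at the floor on both arrays, which held the list median at 0.00. Over the 13 with a ratio it was 0.39 (percentile 100). Against callus, the median of the 4 genes at day 9 was -0.77 in low medium (percentile 0.250) and 0.19 in high medium, within the central 95%. Between media at day 9, chloroplast-encoded genes had a median of -0.04, within the central 95%, with 38 of 69 lower in high medium. The phloem marker OPS had log2 ratios of at least 1.18 at day 5 and 0.02 at day 9. ACR4, EXPA7 and CLV3, markers of epidermis, root and shoot meristem, gave no ratio in any comparison.

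In all, 174 probe sets were at least 2-fold higher and 90 lower in high medium at day 5, and 60 and 34 at day 9. With a floor at the 20th percentile the counts were 495 and 487 at day 5 and 252 and 177 at day 9, and with a floor at the 60th percentile 76 and 37 and 21 and 13. The same direction on both days held for 24 higher and 14 lower probe sets, where independent lists would share 0.703 and 0.206. With floors at the 20th and 60th percentiles these were 60 and 36, and 11 and 7. The low medium array of day 5 had the highest scan background, 105 against 69.0 to 82.0 on the other 5 arrays. Spike controls on the high medium array of day 5 had a median of 1.69 times day 0. With day 9 alone, without the day 5 arrays, the count was 94, and with day 5 alone it was 264, alternatives chosen after seeing the data.

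The planned limma fit called 0 of 22746 probe sets, with 1128 at an unadjusted p under 0.05 and a smallest adjusted p of 0.470, but it could not detect simulated changes. The added fit without probe sets at the floor on all 4 arrays called 3 of 14845, with 1378 at an unadjusted p under 0.05. COR47 was 1 of these 3, at a log2 difference of -1.72 between high and low medium and a limma adjusted p of 0.0489. The other 2 are probe sets unnamed here, 254805_at and 253191_at, both higher in high medium. The log2 difference of 254805_at was above 3, larger in size than that of any named gene, and that of 253191_at was 1.57. The planned filter, which kept probe sets above the floor on at least 2 of the 4 arrays, called 0, with a smallest adjusted p of 0.0517. Over all genes tested, the planned fit called 0 members of any list. Adjusted over the list alone, it called 1 gene each of the osmotic stress list, the secondary wall genes by locus and the beta-glucosidases. Of these, only the first list was fixed beforehand. The adjustment was made within each of 32 lists and not across them, so some such calls can arise by chance.

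The next comparisons asked what differed from day 0 callus after 2, 5 and 9 days in high medium. Among named genes, small heat-shock genes, whose proteins bind unfolded proteins, led at every time. Of the probe sets called in these comparisons, 48.7% to 50.3% are unnamed here and were not ranked. AT1G53540 read 9.10 at day 0, below the floor, and 812, 2345 and 1038 at days 2, 5 and 9, log2 ratios of at least 5.04, 6.57 and 5.39. AT2G29500 read 22.5, 687, 1706 and 1082, and AT1G54050 read 60.1, 1694, 2341 and 1169. AT1G52560 was higher by at least 3.67, 5.63 and 4.57 on the log2 scale, and AT5G48570, an immunophilin gene, by 4.13, 5.05 and 3.79. HSP22 and HSP23.5, the 2 measured genes of the heat shock list fixed beforehand, had log2 ratios at day 5 of at least 5.36 and of 3.68. In a wider list of heat-shock and chaperone genes, written after this was seen, 13, 16 and 14 of 22 measured genes were at least 2-fold higher at days 2, 5 and 9, with medians of 1.36, 2.79 and 1.86. Hsp70-2, a chaperone gene of the same list, had a log2 ratio of -1.02 at day 2. The 3' over 5' ratio of the GAPDH control was 0.969 at day 0 and 1.06, 1.09 and 1.09 at days 2, 5 and 9.

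**Figure D2:**
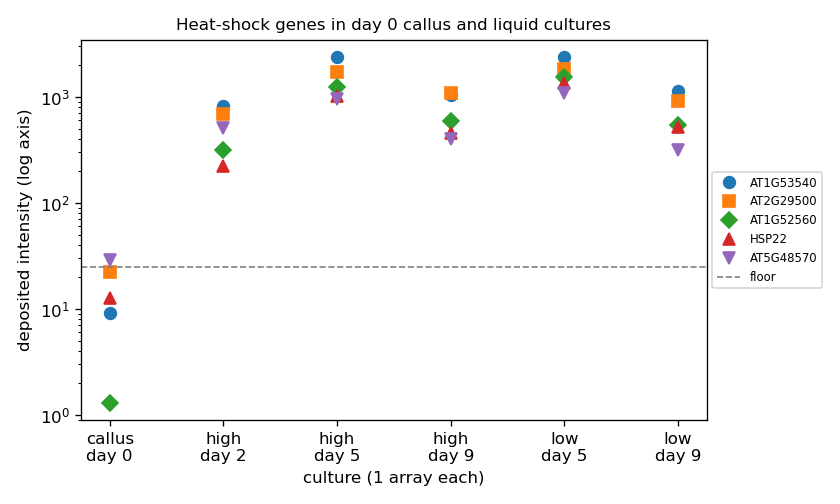
Deposited intensity on a log axis for 5 heat-shock genes in the 6 cultures, with 1 point per array and the floor of 24.7 as a dashed line. AT1G53540 read 9.10 in day 0 callus and 812 to 2349 in the liquid cultures.

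In high medium at day 2 the secondary wall genes by locus reached their highest median against day 0, at 0.77 (percentile 100), with 6 of 21 members at least 2-fold higher. The median was 0.12 at day 5 and 0.00 at day 9, and with a floor at the 60th percentile it was 0.00 at each of these times. AT3G27200 read 157 at day 0 and 641 at day 2, AT1G79620 read 28.2 and 155, and AT5G26330 read 40.7 and 203. C3H14 had a log2 ratio of 1.96 at day 2 and 0.31 at day 9. All 3 measured genes of the secondary wall list fixed beforehand, IRX10, IRX15 and IRX15L, read higher at day 2, with log2 ratios of 0.55, 0.34 and 0.77, and each read lower than day 0 at day 9. Both secondary wall lists had the same median between media at day 5, 0.2219. They may share genes, so they are not separate evidence. ARR15, a cytokinin-induced response regulator gene, lay below the floor at day 0 and read 65.0 at day 2 and 37.8 at day 5. HCT, of lignin biosynthesis, had a log2 ratio of -1.40 at day 2.

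Genes lower than at day 0 in high medium included GSTU25, a glutathione transferase gene, at 612 in callus and 45.5, 50.8 and 48.7 at days 2, 5 and 9. The peroxidase gene AT5G64100 read 305 in callus and 32.2 at day 5, and XTH20, of xyloglucan remodelling, read 285 and 44.6. LTI30, a dehydrin gene, had a log2 ratio of -2.82 at day 2, and AT1G21520 and AT1G43910 had -2.82 and -2.81. AT1G56680 had -3.54 and AT3G28510 at most -2.74 at day 5. AT4G22530 had at most -2.77 and AT4G01870 had -2.62 at day 9. The osmotic stress list, with 4 measured genes, had COR47 and LTI30 at least 2-fold lower at each time. It stood apart at each, with medians of -0.73 at day 5 and -0.79 at day 9. In low medium its medians were -0.25 at day 5, narrowly within the central 95% (percentile 2.57), and -0.24 at day 9 (percentile 1.12). LTI30 was at least 2-fold lower there too, at -1.31 and -1.85, against -1.46 and -1.59 in high medium. COR47 was not, at -0.491 and -0.485. In high medium at day 5, 2 of the 4 members lay at the floor on both arrays, so the medians rest on few genes.

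In low medium the same comparison with day 0 was again led, among named genes, by heat-shock genes. Of the probe sets called there, 47.1% at day 5 and 47.7% at day 9 are unnamed here. AT1G53540 read 2349 at day 5 and 1138 at day 9, and AT2G29500 read 1828 and 907. HSP22 was higher by a log2 ratio of at least 5.76 and 4.38. Of the 22 genes of the wider list, 16 at day 5 and 13 at day 9 were at least 2-fold higher, with medians of 3.21 and 1.56. The 3' over 5' ratio of the GAPDH control was 1.14 and 1.15 on these arrays. GSTU25 lay below the floor at day 5, a log2 ratio of at most -4.63, and read 66.3 at day 9. AT3G60420 had log2 ratios of at most -3.70 and of -2.80, and XTH20 of at most -3.53 and of -2.98. AT3G10080 was lower than in callus by -2.75 and -2.74, while in high medium it had log2 ratios of 0.77, 0.01 and -1.43 at days 2, 5 and 9. The auxin response list had medians of 0.30 and 0.48, with 7 of 8 members higher than in callus on both days, although the day 5 median stood apart only narrowly (percentile 97.6) and not under 5 of the 7 alternatives. In high medium its medians were -0.43 at day 2 (percentile 0.110) and -0.23 and 0.19 at days 5 and 9, within the central 95%. The secondary wall genes by locus had medians of -0.13 and -0.35, and at day 9 the set stood apart (percentile 0.0100), except with a floor at the 60th percentile.

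The list median of mitochondria-encoded genes lay above 0 against callus in all 5 liquid cultures. Of 16 measured, 8 were at least 2-fold higher at day 5 in each medium, with medians of 1.07 in high and 1.10 in low medium, and the medians were 0.34 at day 2, where the list no longer stood apart with a floor at the 60th percentile, and 0.80 and 0.59 at day 9 in high and low medium. The respiratory complex gene cox2 read 45.4 in callus, 270 in high and 335 in low medium at day 5. Chloroplast-encoded genes had medians from 0.17 to 0.58. Between media, the mitochondria-encoded list stood apart at day 9 (0.22) and not at day 5 (-0.08), and the chloroplast-encoded list at day 5 (0.16). The control for 25S ribosomal RNA read 2233 in callus, 2606, 3716 and 2644 in high medium at days 2, 5 and 9, and 3023 and 2517 in low medium at days 5 and 9. Mitosis genes had medians from -0.50 to -0.24 against callus, with 0 of 14 members 2-fold lower.

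Against day 0, 363 probe sets were at least 2-fold higher and 374 lower in high medium at day 2, 419 and 546 at day 5, and 318 and 389 at day 9. In low medium the counts were 448 and 545 at day 5 and 271 and 356 at day 9. All these counts depended on the floor. In high medium at day 5 they were 980 and 1115 with a floor at the 20th percentile, and 257 and 266 at the 60th. With array medians made equal, the share of calls that were higher moved from 49.3% to 59.3% at day 2 and from 43.4% to 54.8% at day 5 in high medium, and it lay above 50% in all 5 comparisons. All 5 liquid cultures shared 110 higher and 107 lower probe sets, against means of 4.37 and 4.91 in simulated unchanged arrays and under 1 for independent lists. At day 5 the media shared 287 higher and 316 lower, against 7.01 and 7.81 simulated and 8.25 and 13.1 for independent lists. Neither reference settles the excess. The simulated arrays share day 0 but hold no real changes, and the independent lists leave the shared array out. Part or much of the excess may therefore come from the single day 0 array, which could not be split.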

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

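The tests of RNA quality, of the day 0 culture, of scan background, of scaling for the secondary wall genes and of other splits were chosen after the results were seen, as was the heat-shock and chaperone list itself. AT5G19110 had a log2 ratio between high and low medium of 1.06 at day 5 and -1.19 at day 9, opposite directions whose difference was not tested. The heat-shock and chaperone list had medians of -0.15 at day 5 and 0.12 at day 9 in the same comparison, again opposite and not tested. Among control probe sets outside the comparisons, 5S ribosomal RNA was at least 3.23-fold above day 0 in high medium at day 5, 5.36-fold in high medium at day 9 and 6.04-fold in low medium at day 9. Spike controls in high medium at day 5 had a median of 1.69 times day 0.

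The median of the heat-shock and chaperone list was higher in all 5 liquid cultures than in day 0 callus, with 13 to 16 of 22 genes at least 2-fold higher and 1 at least 2-fold lower, at day 2. The choice among these scalings is argued against, since the lowest list median over the liquid cultures was 1.40 under quantile scaling or equal medians. Under the main and both other scalings, the median log2 ratio against day 0 of all probe sets with a ratio lay from -0.04 to 0.05. The scalings differed that little, so the test answers for the choice among them only. RNA quality, as 3' over 5' control ratios measure it, moved too little, since the largest change against day 0 was 1.21-fold. These ratios do not answer for other differences in RNA, such as the rise of the 5S ribosomal RNA control on some arrays. A low reading in the day 0 culture stays open, because day 0 has 1 array. The move into liquid medium, with its sugar, mannitol, hormones and shaking, may also account for the pattern and was not tested apart from time.

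The median of the secondary wall genes by locus was higher in high than in low medium on both days, with 5 and 3 of 21 genes at least 2-fold higher and 7 without a ratio on each day. The choice of scaling moved the list little, with a lowest median of 0.19 under quantile scaling or equal medians, against 0.21 in the main setting. Over all probe sets with a ratio, the median between media lay from -0.025 to 0.012 under the main and both other scalings. The scalings differed too little to move the list far, so the test answers for the choice among them only. The higher scan background of the low medium arrays stays open: the lower percentile of the 2 days among matched random lists, 100.0, is the reason the list was weighed and decides nothing, and with a floor at the 60th percentile the list medians were 0.00, since members at that floor count as 0. For the 38 probe sets that differed 2-fold on both days, only 1 of 3 splits of the 4 arrays gave as many, with 30 in the highest other split, which sets day 9 against day 5, and 1 in the crossed split, and 3 splits are too few for a share under 0.05. A difference between media, as the design names it, may account for the pattern and stays open, as does variation between single cultures.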

How the results depend on the processing

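Total counts of 2-fold probe sets stayed within 1.5 times under quantile scaling, equal medians and no floor, although with no floor the lower probe sets fell from 14 to 6 on both days and from 34 to 22 between media at day 9. Counts depended on the floor because dim probe sets cross it. With the floor at the 20th percentile, counts were 982 (media, day 5), 429 (media, day 9), 96 (both days), and against day 0 1347, 2095 and 1334 in high medium at days 2, 5 and 9 and 1992 and 1225 in low medium at days 5 and 9. With the floor at the 60th percentile, they were 113, 34, 18, 401, 523, 420, 586 and 344 in the same order. Without the day 5 arrays the count is that of day 9 alone, 94, and without the day 9 arrays that of day 5 alone, 264, in place of 38 for both days. For limma, 0 calls in the planned fit became 2 with the floor at the 60th percentile, 6 with no day term and 3 without probe sets at the floor on all 4 arrays. For the floor and the day term the cause was not tested. In simulated data, leaving out probe sets at the floor on all 4 arrays raised recovery of 4-fold changes from 0% to 95.5%. In the fit of the real arrays without them, the unadjusted limma p of COR47 went from 0.00184 to 9.88e-06, so fewer tests alone do not account for the calls. Limma called 0 under the other 6 settings. Of 820 alternative values for 2-fold ratios of named genes, 758 stayed 2-fold, 62 fell below and 0 reversed. Of 368 alternative values for lists standing apart, 328 still did and 40 did not, 19 of them with the floor at the 60th percentile, where more members count as 0; 0 reversed. Signal near the floor limits what can be read from dim genes.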

Other observations

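Of 18 expansin genes, 2 were at least 2-fold higher than in callus and 2 lower in high medium at day 2, and 0 were higher and 2 lower in each medium at days 5 and 9, with 7 to 9 at the floor on both arrays. EXPA9 read 194 in callus and 65.6, 41.7 and 53.1 in high medium at days 2, 5 and 9, and EXPA15 read 75.6 in callus and 153, 105 and 93.3. GSTU26 read 159 in callus and 31.1 in high medium at day 5. Tubulin genes had list medians from -0.38 to -0.33 in high medium and in low medium at day 5, and one of -0.12 in low medium at day 9, which did not stand apart.

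Cytosolic ribosomal protein genes had a median log2 ratio between media of 0.17 at day 5, with 62 of 70 members higher in high medium, and of 0.00 at day 9, with 35 higher and 35 lower. Core histone genes had medians of -0.16 at day 5 and -0.07 at day 9, and only the first stood apart. Genes of the endoplasmic reticulum stress list stood apart in none of the 7 comparisons, with medians from 0.02 to 0.27. The cell cycle list, with 3 measured genes, had medians from -0.73 to -0.52 against callus in the 5 liquid cultures and stood apart only in low medium at day 9 (-0.67). The primary wall list, also with 3, had medians from -0.63 to -0.18 and stood apart only in high medium at day 9 (-0.63).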
